A study of Mus musculus with 42 samples.

How the data were processed

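RNA was measured on 42 Affymetrix whole-transcript arrays of mouse reproductive tract tissue, in 14 groups of 3 arrays, 21 female and 21 male. Per the labels' protocols, total RNA was extracted from fresh tissue with a column kit, copied into cDNA, fragmented and labelled with biotin. The mice were 3 to 7 months old, and females were collected in diestrus, per the labels. Each group joins 1 tissue with 1 genotype, taken from the labels, and the labels call the arrays of a group biological replicates. All 42 arrays were used.

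The deposited table held 28856 probe sets as log values, which were taken as log2 values. Every probe set had a median of exactly 0 over the 21 female arrays and again over the 21 male arrays, so each value is relative to the middle array of its sex. Absolute signal was lost, and female and male arrays were never compared. The log base, the summarisation and the normalisation between arrays are not given in the sources used here. The centring was read from the values themselves, the scale (the log base) stays unknown, and the direction was taken as higher for more RNA, which the targeted gene Hoxa11 could test. The median of an array lay between -0.0538 and 0.0371, and the SD of an array between 0.177 and 0.644. For arrays, their number limits the precision, and signal over background is unknown after centring.

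The probe table gave 21789 probe sets 1 gene symbol, 1621 several symbols and 5446 none. Of the probe sets with 1 symbol, 21698 matched the RefSeq gene table of assembly GRCm38.p6 by gene ID. The arrays' own genome build is not named, so that table served only for names and for which genes neighbour each other. Values were averaged over the probe sets of a gene, which gave 19938 genes, of which 18939 had 1 probe set and 999 had more. The plan had been to take the probe set with the highest mean, but centring makes that choice meaningless. The mean, planned as an alternative, took its place, and the highest-mean rule was run as an added alternative. A filter on dim probe sets was also planned and not run, because no signal over background is left, and a filter on spread was added instead.

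Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, no trend) on all arrays of a tissue, or of a sex where tissues were compared. P-values were adjusted by Benjamini-Hochberg over the 19938 genes, and a gene was called at an adjusted p below 0.05. These p-values measure the spread between these samples. Each mutant was compared with WT of its tissue. Further contrasts were DKO against AKO, AKDH against AKO and AHDK against DKO, an F test over the 4 mutants, the difference of the AKO effect between 2 tissues of a sex, and WT tissue against WT tissue. The tests, the comparisons, the alternatives of the first kind and 38 gene lists were fixed before the data were examined.

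Segment lists were genes with an adjusted p below 0.01 and an absolute log2 difference of at least 2 between WT oviduct and WT uterus, or between WT epididymis and WT vas deferens. Their shift in a mutant is the mean log2 change over the list, with the SE from the 3 mutant and 3 WT arrays. It was tested with limma's camera (preset correlation 0.01, and estimated) and, per array, with a two-sided exact permutation test of 3 against 3 arrays, whose smallest p is 0.1. Gene lists were tested with camera in the 10 mutant against WT comparisons, 380 tests adjusted together, and members were counted as called over all genes and adjusted over the list alone. The genes named were the 6 targeted genes, the largest rises and falls among called genes whose mutant and control values did not overlap (10 and 10 for AKO against WT, 6 and 6 for other mutants against WT, 4 and 4 elsewhere), and up to 4 members of each list with the smallest adjusted p per comparison, called or not. Names of uncharacterised transcripts, olfactory receptors and most small RNAs (Y RNAs were not among them) were passed over, and where fewer genes met the rule all of them were taken. Sex-linked and ovary genes of the oviduct arrays, and genes named to show how a set behaves in another comparison, were chosen after their values were seen.

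Overlaps of calls between mutants of a tissue share their WT arrays. They were set beside n1 x n2 / N per direction and beside 20 simulations in which every array, WT included, was drawn with each gene's own SD and no change. Genes within 20 Mb of the Hoxa or the Hoxd cluster were compared with all other genes by two-sided Fisher's exact tests.

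The replicate numbers of the titles were tested as pairs by correlating, over genes, the arrays with the same number in 2 groups after their group means were removed. In 4 of 42 pairs of groups all 3 correlations exceeded 0.1. These were AKO uterus with AKO oviduct, WT with AKO oviduct, WT vas deferens with WT epididymis, and AKO vas deferens with AKO epididymis. Apart from WT with AKO oviduct, they join tissues of the same genotype, where the same animals could have given both. Among such pairs only WT uterus with WT oviduct failed (lowest correlation -0.07). The labels do not say that animals were shared, and the main fits between tissues treated the arrays as unpaired. The replicate block (the number as a term of the fit) was run as an alternative for every comparison.

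Other settings chosen at the start were quantile normalisation between arrays, an eBayes trend, a fit of the 6 arrays compared, the replicate block, each array left out in turn, an estimated camera correlation, other list thresholds, lists chosen and measured on different WT arrays (cross-fitted), and windows of 10 and 40 Mb. Settings chosen after seeing the data were the spread filter, 2 other probe set rules, array scores as covariates (small RNA genes, oestrogen-responsive genes, adipocyte and skeletal muscle genes), a replicate block within genotype, the removal of olfactory receptor genes from the windows and of targeted genes from the segment lists, and fits without 3 libraries that stand apart. Those 3 are the libraries labelled WT oviduct replicate 2, AKDH vas deferens replicate 3 and AKO epididymis replicate 1. The small RNA score is the mean of 364 genes of small nuclear, small nucleolar and similar RNAs. At most 100 regroupings of the arrays were drawn for each test of other splits.

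The fit was tested on simulated data of independent arrays, with 200 of 19938 genes, drawn at random, changed. At a log2 change of 1 it recovered 84% of them for uterus AKO against WT, 89.5% for vas deferens, 72% for oviduct and 84% for epididymis. For the difference of the AKO effect between tissues it recovered 74.5% in females and 77.5% in males. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.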

Results

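The 42 arrays held 14 groups of 3. Female tracts were uterus (WT, AKO, DKO, AKDH and AHDK) and oviduct (WT and AKO), and male tracts were vas deferens (the same 5 genotypes) and epididymis (WT and AKO). AKO lacks Hoxa9, Hoxa10 and Hoxa11, DKO lacks Hoxd9, Hoxd10 and Hoxd11, AKDH adds 1 mutant Hoxd copy to AKO, and AHDK adds 1 mutant Hoxa copy to DKO. Changes are log2 differences between group means with their SE, and a gene was called at a limma adjusted p below 0.05 over 19938 genes. The largest rises and falls named separated all 3 mutant arrays from all 3 WT arrays.

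Hoxa11 told AKO and AKDH apart from WT in uterus and vas deferens. In uterus its values were 2.75, 1.23 and 2.19 in WT, -1.59, 0.67 and -0.59 in AKO, and -1.57, -0.61 and 0 in AKDH. Vas deferens gave 1.38, 1.17 and 0.43 in WT, -0.37, -0.55 and -0.63 in AKO, and -0.44, -0.71 and -0.84 in AKDH. Hoxa11 fell in vas AKO (-1.51, SE 0.31, adjusted p = 0.00961), vas AKDH (-1.66, adjusted p = 0.0027) and uterus AKDH (-2.78, SE 0.56, adjusted p = 0.0161). It was lower but not called in uterus AKO (-2.56, adjusted p = 0.112) and epididymis AKO (-0.99, adjusted p = 0.107). Oviduct AKO gave Hoxa11 -0.56 (adjusted p = 0.993), from a WT mean of -1.34 that was already low. Hoxa10 fell in vas AKDH (-0.86, adjusted p = 0.0243) and Hoxd11 fell there too (-0.60, adjusted p = 0.0269).

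Hoxd9 told DKO and AHDK apart from WT in vas deferens only. Its group means there were -0.19 in WT (SD 0.06), -0.74 in DKO (SD 0.16), -0.68 in AHDK (SD 0.02) and 0.26 in AKO (SD 0.14). In AKDH, with 1 mutant Hoxd copy, the mean was -0.02 (SD 0.07), not below WT, so Hoxd9 did not mark that genotype against WT. Against AKO, which AKDH differs from by that copy, the AKDH values (0, 0.04 and -0.09) all lay lower (AKO 0.41, 0.23 and 0.15). Compared with WT, Hoxd9 fell in DKO (-0.55, SE 0.08, adjusted p = 0.00581) and AHDK (-0.49, adjusted p = 0.00885) and rose in AKO (0.45, adjusted p = 0.0053). In uterus DKO, Hoxd9 (-0.12), Hoxd10 (0.18) and Hoxd11 (-0.17) were not called, and Hoxa9 was called in no mutant. Each targeted gene had 1 probe set, whose place within the gene is not given in the sources used here. In uterus AHDK, Hoxd11 (-0.21, 0 and 0.25) lay below all WT values (1.02, 0.36 and 1.19), but its change of -0.84 was not called (adjusted p = 0.183). A probe outside a deleted part checks nothing, so no called target checks the labels of uterus DKO, uterus AHDK and oviduct AKO. No target was called in uterus AKO either, but its Hoxa11 values all lay below those of WT.

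**Figure D1:**
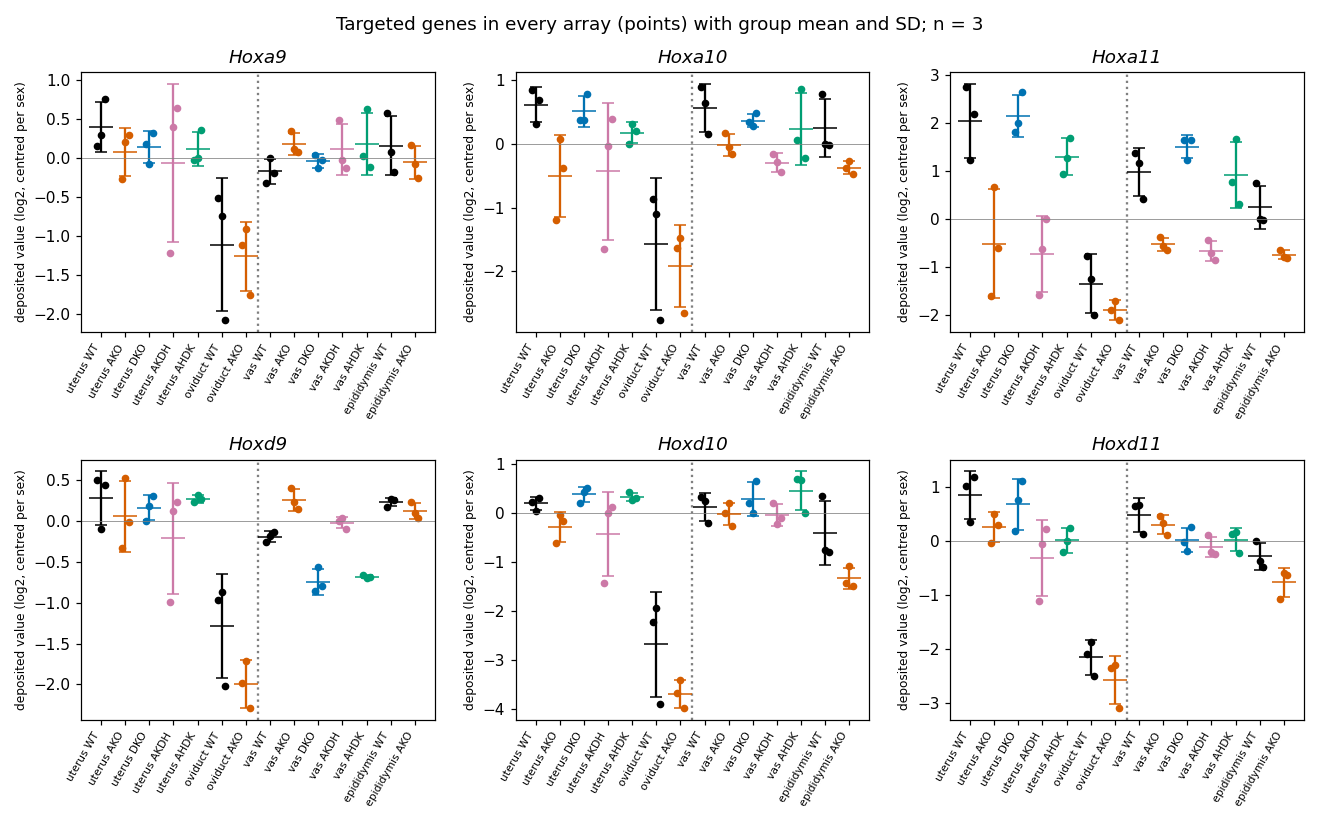
Values of the 6 targeted genes (vertical axis, log2 centred per sex) in every array, by tissue and genotype, with group mean and SD. Hoxa11 was low in AKO and AKDH, and Hoxd9 was low in DKO and AHDK of the vas deferens.

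Of the 42 libraries, 3 were treated as standing apart. In the library labelled WT oviduct replicate 2, Xist, the RNA of the inactive X, was -5.92, and the Y genes Eif2s3y and Uty were 2.09 and 1.77. Its ovary list mean was 2.06, and the highest other oviduct array had 0.41. The library labelled AKDH vas deferens replicate 3 had 1.51 for sperm genes and 1.10 for motile cilia genes. The library labelled AKO epididymis replicate 1 had 3.39 for proximal epididymis genes, where the other AKO epididymis arrays had 0.70 and 0.73. Adipocyte genes were -0.85, -0.49 and -0.02 in WT vas, 0.49, 0.15 and 1.00 in AKO, -0.16, -0.41 and -0.26 in DKO, 1.08, 0.84 and 0.88 in AKDH, and 0.94, 1.23 and 0.64 in AHDK.

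WT oviduct and WT uterus differed in 4770 genes, 2898 higher in oviduct and 1872 lower (limma; 2955 without oviduct WT replicate 3). Oviduct was highest above uterus for the ciliary gene Sntn (6.23), Timp4 (6.15), Stoml3 (5.88) and Rsph4a (5.69). Uterus was higher for Clca1 (-3.63), Hoxa11 (-3.39), Prap1 (-3.33) and Plac8 (-3.05). WT epididymis and WT vas differed in 5602 genes, 2243 higher in epididymis and 3359 lower. Epididymis was higher for Defb22 (6.05), Defb38 (5.98), Crisp4 (5.90), Car4 (5.86), Rnase9 (5.66) and Npy (5.27). Vas was higher for Abcg2 (-5.70), Crygc (-5.09), Kcnj16 (-4.87) and Cdkl1 (-4.48). These differences gave 347 oviduct-high, 22 uterus-high, 216 epididymis-high and 84 vas-high genes.

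In uterus AKO, Rxfp2, the receptor of insulin-like 3, fell most (-2.78, SE 0.25, adjusted p = 0.00187). Robo2, a Slit receptor, fell by 2.61, Aldh1a2, which makes retinoic acid, by 1.46, and Tnfaip6, a hyaluronan-binding protein, by 1.43. The uroplakin Upk1a rose (2.63, SE 0.40, adjusted p = 0.0366), as did Hoxc10 (1.86), Hoxc8 (1.46) and the growth factors Fgf16 (1.58) and Fgf18 (1.31, adjusted p = 0.00374). Of 18 called genes, 8 rose and 10 fell (5 and 15 after quantile normalisation). With 1865 genes at an unadjusted p below 0.05, 12.8% of genes had AKO values apart from WT values, against 10% by chance. Each of the 6 arrays moved the count of 18 by more than 1.5 times: it was 40, 7 and 5 without WT replicates 1, 2 and 3, and 2, 8 and 4 without AKO replicates 1, 2 and 3.

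Among 39 other Hox genes and cluster neighbours in uterus AKO, 2 rose (Hoxc10 and Hoxc8), or 9 rose and 2 fell adjusted over the list alone (mean 0.25, camera adjusted p = 0.0156, and 0.989 with an estimated correlation). The FGF list of 20 genes held 1 rise, Fgf18, or 3 over the list alone (mean 0.35, adjusted p = 0.00681, and 0.989 estimated). Of 6 targeted genes 0 were called by limma, and 1, Hoxa11, fell over the list alone (mean -0.88, adjusted p = 0.00265, and 0.989 estimated). Adipocyte genes had 0 of 19 called by limma both ways (mean 0.47, adjusted p = 0.014, and 0.989 estimated); the mean was 0.73 and 0.29 without WT replicates 1 and 3, and 0.70 and 0.18 without AKO replicates 2 and 3. With an estimated correlation, which camera measures within each list, 0 of the 63 list calls against WT remained in any tissue.

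In uterus AKDH, Rxfp2 (-3.32, SE 0.25, adjusted p = 0.000149), Robo2 (-2.83), the thyroid hormone deiodinase Dio2 (-2.19) and the anion transporter Slc26a7 (-2.19) fell. Rtn1, a reticulon (3.56, SE 0.41, adjusted p = 0.00158), and Fgf1 (3.19) rose most, followed by Meig1 (2.60) and Lrrc26 (2.59). Hoxc8 (2.02), Hoxc10 (2.02), Wnt2b (2.03), Fgf18 (1.39) and the Wnt antagonist Sfrp1 (1.39) rose, and Lef1 (-1.69), Eya1 (-1.48), Hand2 (-1.40) and Aldh1a2 (-1.31) fell. In all, 1311 genes were called, 783 up and 528 down (4528 at an unadjusted p below 0.05; 26.7% apart, 10% by chance). The count was 639 without WT replicate 2, 686 without WT replicate 3, 783 without AKDH replicate 1 and 530 without AKDH replicate 3. Of the other Hox genes 8 rose and 2 fell, or 13 and 3 over the list alone (mean 0.27, camera adjusted p = 0.035, and 0.989 estimated). The FGF list held 4 rises both ways (mean 0.40, adjusted p = 0.0263, and 0.989 estimated). The targeted genes held 1 fall of 6, or 2 over the list alone (mean -1.10, adjusted p = 0.0132, and 0.989 estimated; -0.61 without AKDH replicate 1).

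In uterus DKO, Retnlg, a resistin-like protein of neutrophils, rose most, by 3.45 (SE 0.67, adjusted p = 0.0397), the eotaxin receptor Ccr3 by 2.30, the lectin Cd209f by 2.26, and Ccl6 by 1.81. H2-Aa (1.32) and Cd74 (0.66) of the class II pathway and Sfrp1 (1.80, adjusted p = 0.000918) also rose. Snhg17 (-1.04), Usp31 (-0.94), the tight junction gene Cldn8 (-0.85) and the cell cycle inhibitor Cdkn1b (-0.75) fell. Of 194 called genes, 124 rose and 70 fell, and after quantile normalisation 4 rose and 8 fell (3048 at an unadjusted p below 0.05; 20.9% apart, 10% by chance). The count was 23, 2 and 3 without WT replicates 1, 2 and 3, and 14 and 6 without DKO replicates 2 and 3.

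The macrophage and dendritic cell list in uterus DKO held 2 rises among 25 genes (H2-Aa and Cd74), or 16 over the list alone (mean 0.61, camera adjusted p = 7.26e-09, and 0.989 with an estimated correlation). Neutrophil and eosinophil genes held 2 of 18 (Retnlg and Ccr3), or 5 over the list alone (mean 0.71, adjusted p = 0.00376, and 0.989 estimated), with a mean of 0.42 without DKO replicate 1. B and plasma cell genes had 0 of 14 called by limma and 1 over the list alone (mean 0.38, adjusted p = 0.0215, and 0.989 estimated), with a mean of 0.25 and 0.57 without DKO replicates 1 and 2. For cell cycle genes both counts were 0 of 31, although 31 were above WT (mean 0.49, adjusted p = 0.0436, and 0.989 estimated), and the mean was 0.16 without WT replicate 1.

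In uterus AHDK, Kap, the kidney androgen-regulated protein, rose most (4.31, SE 0.40, adjusted p = 0.000768). Retnlg (3.70), Serpina1c (3.28), Peg10 (2.72), Il1a (2.56) and Ccr3 (2.42) followed, and Hoxc10 (1.75) and Sfrp1 (1.71) rose too. Rxfp2 (-2.83, SE 0.25, adjusted p = 0.000539), Krt23 (-2.14), Cldn8 (-1.94, SE 0.15, adjusted p = 0.000325), Gpx2 (-1.61) and Eya1 (-1.30) fell. Of 704 called genes 458 rose and 246 fell (4260 at an unadjusted p below 0.05; 29.6% apart, 10% by chance). The count was 355, 467 and 172 without WT replicates 1, 2 and 3, and 31 and 151 without AHDK replicates 1 and 3.

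Of 25 macrophage and dendritic cell genes in uterus AHDK, 10 rose, among them Adgre1 (1.48), H2-Aa (1.58) and Cd74 (0.93), or 20 over the list alone (mean 0.84, camera adjusted p = 1.41e-14, and 0.989 with an estimated correlation). Interferon response genes gave 8 rises of 32, among them Oasl1 (1.54), Zbp1 (1.51) and Oas3 (1.21), or 20 over the list alone (mean 0.71, adjusted p = 5.51e-13, and 0.989 estimated). Neutrophil and eosinophil genes held 2 of 18, or 5 over the list alone (mean 0.85, adjusted p = 0.0023, and 0.989 estimated). Oestrogen-responsive genes held 1 of 25, or 5 (mean 0.99, adjusted p = 0.00187, and 0.989 estimated), and luminal epithelium genes 2 of 24, or 6 (mean 0.54, adjusted p = 0.00418, and 0.989 estimated). Complement genes held 2 of 27, or 4 (mean 0.64, adjusted p = 0.0176, and 0.989 estimated), and T, NK and mast cell genes 1 of 25, or 3 (mean 0.36, adjusted p = 0.0156, and 0.989 estimated). Motile cilia genes were lower (mean -0.08, and -0.13 without AHDK replicate 2; adjusted p = 0.0443, and 0.989 estimated), while the 1 called member, Ak8, was higher.

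**Figure D2:**
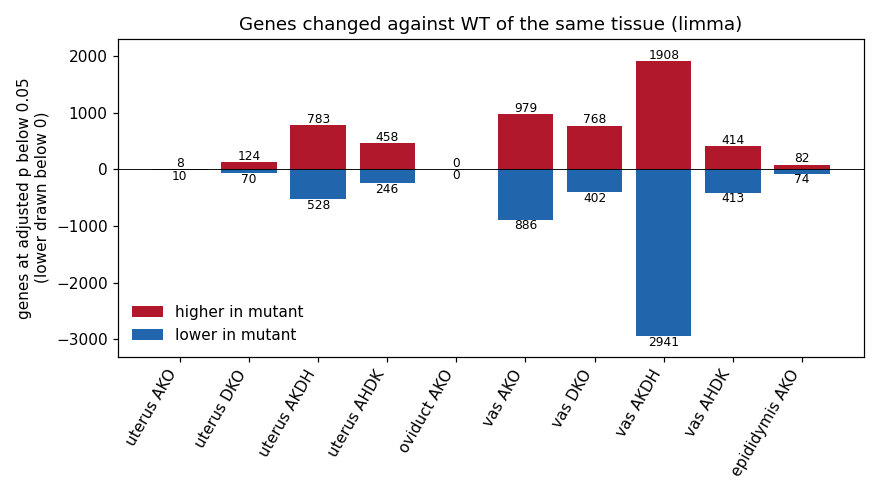
Number of genes called against WT of the same tissue (vertical axis, lower genes drawn below 0) in the 10 mutant groups. Vas AKDH had the highest count, 4849, and oviduct AKO had 0 (609 at an unadjusted p below 0.05, limma).

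**Figure D3:**
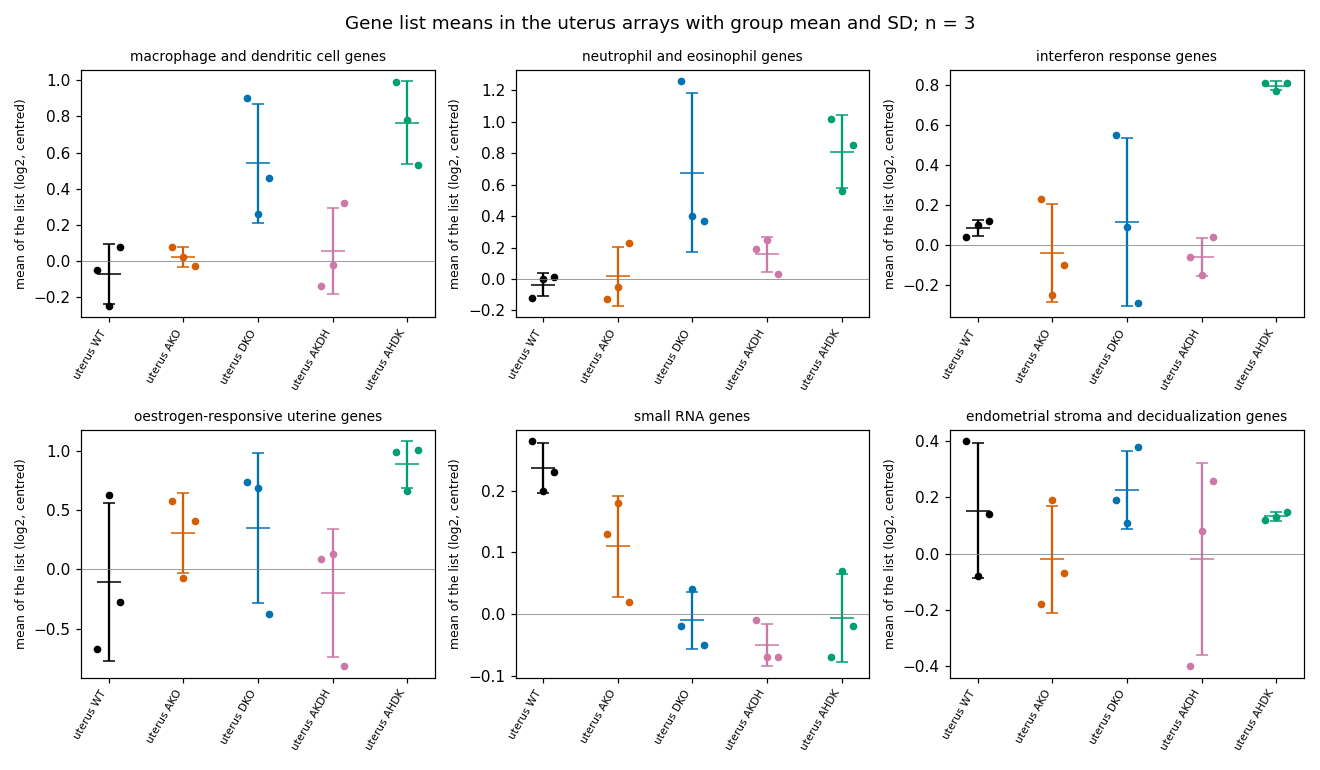
Mean of 6 gene lists (vertical axis, log2) in each uterus array, with group mean and SD. Macrophage and neutrophil genes were above WT in DKO and AHDK, interferon genes in AHDK, and small RNA genes were highest in WT.

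Small RNA genes set WT uterus apart from the mutants. Their mean was 0.28, 0.20 and 0.23 in WT, 0.13, 0.18 and 0.02 in AKO, -0.02, 0.04 and -0.05 in DKO, -0.01, -0.07 and -0.07 in AKDH, and -0.07, 0.07 and -0.02 in AHDK. With this score as a covariate 9 genes were called in uterus AKO, 0 in DKO, 1 in AKDH and 0 in AHDK (limma). Rxfp2 was then -2.66 in AKO, still called, and -3.05 in AKDH and -2.60 in AHDK, not called. Retnlg was 1.08 in DKO and 1.34 in AHDK under that covariate, and Ccr3 was 1.24 and 1.36. No AKO, DKO, AKDH or AHDK array reached the WT range of the score (AKO came closest, with 0.18), so score and genotype were confounded in each of them.

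The 22 uterus-high genes, among them Rxfp2, Robo2 and Dio2, were lower in uterus AKO (mean -1.09, SE 0.17, 40.8% of the difference between WT uterus and WT oviduct; 2 called down, 0 up by limma) and AKDH (-1.57, SE 0.23, 58.9%; 9 called down, 0 up). Camera gave adjusted p = 2.8e-14 in AKO and 6.57e-14 in AKDH with the preset correlation, and 0.0016 in each with an estimated one (permutation p = 0.1, the smallest that 3 against 3 arrays can give). Of the 22, 4 were targeted genes (Hoxa10, Hoxa11, Hoxd10 and Hoxd11), and the other 18 had means of -1.07 in AKO and -1.61 in AKDH (preset adjusted p = 7.07e-12 and 2.34e-12, estimated 0.00221 in each). With lists chosen and measured on different WT arrays, uterus-high genes had a mean of -0.35 in AKO, no longer called at the preset correlation, -0.82 in AKDH, still called, and 0.40 in DKO, the other direction. On the same WT arrays all 22 had a mean of -0.30 in DKO (preset adjusted p = 0.0316, estimated 0.27) and -0.37 in AHDK (preset 0.106, estimated 0.366). Without WT uterus replicates 2 and 3 these were -0.53 and -0.63 in DKO and -1.11 and -0.66 in AHDK, without oviduct WT replicate 3 they were -0.07 and -0.21, and AHDK had -0.21 without WT uterus replicate 1 and -0.59 without oviduct WT replicate 1. In oviduct AKO the mean of these uterus-high genes was -0.29 (preset 0.00117, estimated 0.366), and it was 0.02 without oviduct WT replicate 1, -0.46 without oviduct WT replicate 3 and -0.14 without oviduct AKO replicate 3. The 347 oviduct-high genes were 0.19 in uterus AKO (6.02%; 3 called up; preset 0.00498, estimated 0.389) and 0.28 in AKDH (9.07%; 50 up, 3 down; preset 0.00045, estimated 0.366), and 0.12 and 0.20, neither called, with different WT arrays. The median change of the oviduct-high genes was 0.03 in uterus AKO and 0.03 in AKDH, so a part of the list carried those means. Fgf1 (2.90), Wnt2b (2.95), Rtn1 (3.99), Upk1a (4.32), Hoxc8 (3.46) and Sfrp1 (1.88), which rose in AKDH, were higher in WT oviduct than in WT uterus, and Hoxc10 was not called there (0.48, adjusted p = 0.336). The oviduct-high genes had a mean of 0.06 in AHDK with a median of -0.03 and a test direction of down, and 0.03 in DKO with a test direction of down (preset adjusted p = 0.901 and 0.628, estimated 0.967 and 0.949).

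In vas AKO, Rnase9, a ribonuclease-like secretory gene of the epididymis (4.57, SE 0.45, adjusted p = 0.000193), Gpr82 (4.13, SE 0.33, adjusted p = 5.53e-05), Gpx5 (4.01), the seminal vesicle gene Svs3b (3.66) and the protease inhibitor Eppin (3.56) rose most. The aldo-keto reductase Akr1cl (-3.91, SE 0.22, adjusted p = 3.45e-06), Eci3 (-3.71), Cdkl1 (-3.33), the phosphatase Ptprz1 (-3.19) and the neuropeptide Nmu (-3.18) fell most. The Wnt feedback genes Znrf3 (1.30) and Axin2 (1.22) rose, and the protamines Prm1 (-2.82) and Prm2 (-2.89) and Eya1 (-1.83) fell. Of 1865 called genes, 979 rose and 886 fell (4585 at an unadjusted p below 0.05; 33.1% apart, 10% by chance), 2278 were called without the libraries that stood apart, and 345 with adipocyte and skeletal muscle scores as covariates. The count was 1018 without WT replicate 2, 1082 without AKO replicate 1 and 1243 without AKO replicate 3.

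Smooth muscle genes gave 6 falls of 32 in vas AKO, among them Actg2 (-0.71) and Cnn1 (-0.73), or 21 over the list alone (mean -0.61, camera adjusted p = 7.77e-08, and 0.989 with an estimated correlation). The list of cauda epididymis and vas epithelial genes gave 11 rises and 1 fall of 29, with Car4 (2.52) among the rises, or 15 and 1 over the list alone (mean 0.64, adjusted p = 1.49e-07, and 0.989 estimated). Adipocyte genes gave 12 rises of 19, among them Gpd1 (2.02), Cd36 (1.66) and Lpl (1.52), or 14 over the list alone (mean 1.00, adjusted p = 1.16e-08, and 0.989 estimated). Proximal epididymis genes gave 8 rises and 1 fall of 38, or 12 and 3 (mean 0.58, median 0.09, adjusted p = 0.00418, and 0.989 estimated), and seminal vesicle and prostate genes 3 rises of 17 both ways (mean 1.09, adjusted p = 0.0443, and 0.989 estimated). The retinoic acid list of 15 genes held 2 rises, Aldh1a1 (0.63) and Crabp2 (1.30), or 8 rises and 1 fall over the list alone (mean 0.43, adjusted p = 0.000524, and 0.989 estimated).

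In vas AKDH, Rnase9 (4.36), Gpr82 (4.19), Eppin (3.81) and Spink13 (3.56) rose, and Cdkl1 (-4.29, SE 0.18, adjusted p = 3.17e-07), Eci3 (-4.29), Akr1cl (-4.25), Ptprz1 (-4.23), the defensin Defb30 (-3.81) and Nmu (-3.35) fell. Znrf3 (1.70), Axin2 (1.28) and Shh (1.13) rose. In all 4849 genes were called, 1908 up and 2941 down (2020 and 1818 after quantile normalisation; 7547 at an unadjusted p below 0.05; 41.5% apart, 10% by chance). Without the library labelled AKDH vas replicate 3 there were 4708 (2172 up, 2536 down), without WT replicate 2 there were 3032, and with adipocyte and skeletal muscle scores as covariates there were 266. Smooth muscle genes gave 21 falls of 32, or 24 over the list alone (mean -0.78, camera adjusted p = 6.79e-06, and 0.989 with an estimated correlation). Cauda epididymis and vas epithelial genes gave 18 rises and 1 fall of 29 both ways (mean 0.83, adjusted p = 6.54e-08, and 0.989 estimated), and adipocyte genes 15 rises of 19, or 16 (mean 1.38, adjusted p = 1.1e-09, and 0.989 estimated).

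Smaller list changes in vas AKDH were counted over all genes and then over the list alone. Retinoic acid genes gave 5 rises and 1 fall of 15, or 6 and 1 (mean 0.32, camera adjusted p = 0.0154, and 0.989 with an estimated correlation), and cell cycle genes 4 rises of 31, or 3 (mean 0.35, adjusted p = 0.000425, and 0.989 estimated). Motile cilia genes gave 5 rises and 3 falls of 61, or 5 and 2 (mean 0.36, adjusted p = 0.00418, and 0.989 estimated). Interferon genes gave 2 rises and 9 falls of 32, or 2 and 14 (mean -0.32, adjusted p = 0.0109, and 0.989 estimated), and T, NK and mast cell genes 6 falls of 25 both ways (mean -0.30, adjusted p = 0.0291, and 0.989 estimated). The motile cilia score was 1.10 in the library labelled AKDH vas replicate 3, and without it the mean change was -0.05, so that rise rested on 1 array (0.59 and 0.55 without AKDH replicates 1 and 2). For cell cycle genes the mean was 0.23 without AKDH replicate 1.

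In vas DKO, Cartpt, a neuropeptide gene (2.08, SE 0.23, adjusted p = 0.00201), Cyp4b1 (1.86), Gpr82 (1.77), Fgf1 (1.55) and the splicing gene Cwc22 (1.51) rose, and the Y RNA Rny1 (-1.62), the sialyltransferase St8sia6 (-1.36) and Nmu (-1.03) fell. Of 1170 called genes 768 rose and 402 fell (194 and 244 after quantile normalisation; 4118 at an unadjusted p below 0.05; 30.0% apart, 10% by chance; 1550 without the libraries that stood apart; 254 with adipocyte and skeletal muscle scores as covariates). The count was 389 and 238 without WT replicates 1 and 2, and 268, 384 and 375 without DKO replicates 1, 2 and 3. Interferon genes gave 1 rise and 6 falls of 32, or 2 and 7 over the list alone (mean -0.15, and -0.06 without WT replicate 1; camera adjusted p = 0.00246, and 0.989 with an estimated correlation). Macrophage genes gave 1 fall of 25, Ms4a7 (-0.86), and 0 over the list alone (mean -0.35, adjusted p = 7.52e-05, and 0.989 estimated). Skeletal muscle genes (mean -0.59, and -0.25 without WT replicate 3; adjusted p = 0.0109, and 0.989 estimated) and cell cycle genes (mean -0.17, and -0.09 without WT replicate 1; adjusted p = 0.013, and 0.989 estimated) had 0 called by limma both ways. Oestrogen-responsive genes held 1 fall, Sprr2f (-0.64), and 0 over the list alone (mean -0.12, adjusted p = 0.0291, and 0.989 estimated).

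In vas AHDK, the protease inhibitor Serpina3b (3.09, SE 0.38, adjusted p = 0.00221), Gpr82 (2.74), B3galt2 (2.53), adiponectin (Adipoq, 2.33, adjusted p = 0.0136) and Rnase9 (2.31) rose. Pilra (-2.54), Ctla2a (-1.64), Cdkl1 (-1.34) and Nmu (-1.11) fell. Of 827 called genes 414 rose and 413 fell (3520 at an unadjusted p below 0.05; 21.5% apart, 10% by chance; 1076 without the libraries that stood apart; 1 with adipocyte and skeletal muscle scores as covariates). The count was 431 and 245 without WT replicates 1 and 2, and 452 and 464 without AHDK replicates 1 and 3. Adipocyte genes gave 13 rises of 19, among them Cd36 (2.18) and Lpl (2.05), or 15 over the list alone (mean 1.39, camera adjusted p = 5.92e-16, and 0.989 with an estimated correlation). Cauda epididymis and vas epithelial genes gave 1 rise of 29, or 3 (mean 0.25, and 0.16 and 0.14 without WT replicate 2 and AHDK replicate 3; adjusted p = 0.00211, and 0.989 estimated). Skeletal muscle genes had 0 of 22 called by limma both ways (mean -0.78, and -0.44 without WT replicate 3; adjusted p = 0.00211, and 0.989 estimated). Cell cycle genes also had 0 called both ways (mean 0.16, adjusted p = 0.035, and 0.989 estimated), with a mean of 0.01 and 0.31 without AHDK replicates 1 and 2 and 0.09 without WT replicate 3. Other Hox genes were higher (1 rise both ways; mean 0.14, adjusted p = 0.0132, and 0.989 estimated). Extracellular matrix genes held 2 rises both ways (mean 0.15, adjusted p = 0.0205, and 0.989 estimated), with a mean of 0.23 and 0 without WT replicates 1 and 3, and 0.25, -0.04 and 0.23 without AHDK replicates 1, 2 and 3.

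Vas-high genes, among them Cdkl1, Eci3, Ptprz1 and Nmu, fell in vas AKO (mean of 84 genes -1.25, SE 0.09, 43.8% of the difference between WT vas and WT epididymis; 60 fell, 1 rose) and in vas AKDH (-1.53, SE 0.10, 53.7%; 68 fell, 2 rose). Camera gave adjusted p = 9.58e-36 and 3.72e-25 with the preset correlation, and 0.0016 and 0.00378 with an estimated one. The 216 epididymis-high genes, among them Rnase9, Eppin and Gpr82, were higher in vas AKO (1.17, SE 0.14, 39.3%; 113 rose, 2 fell; preset 5.72e-40, estimated 0.0564) and AKDH (1.33, SE 0.14, 44.6%; 138 rose, 5 fell; preset 9.8e-36, estimated 0.064). In AHDK they were 0.63 (SE 0.27, 21.1%; 27 rose; preset 2.56e-21, estimated 0.15), and vas-high genes were -0.36 (SE 0.03, 12.6%; 7 fell; preset 1.03e-06, estimated 0.13). Without AHDK replicate 3 the first of these was 0.41, and without WT vas replicate 3 the second was -0.59. DKO gave 0.13 (SE 0.24, 4.2%; preset 0.461, estimated 0.949) and -0.13 (SE 0.05, 4.44%; preset 0.0194, estimated 0.38). With 1 array left out the first ran from -0.01 without DKO replicate 2 to 0.33 without DKO replicate 1, and the second from -0.29 without WT replicate 3 to -0.08 without DKO replicate 2. The permutation p was 0.1, the smallest possible, for each of these means except 0.5 for epididymis-high genes in DKO. Both lists were chosen on the WT vas arrays that are also the control here. That can enlarge these shifts, their shares of the WT difference and their tests.

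**Figure D4:**
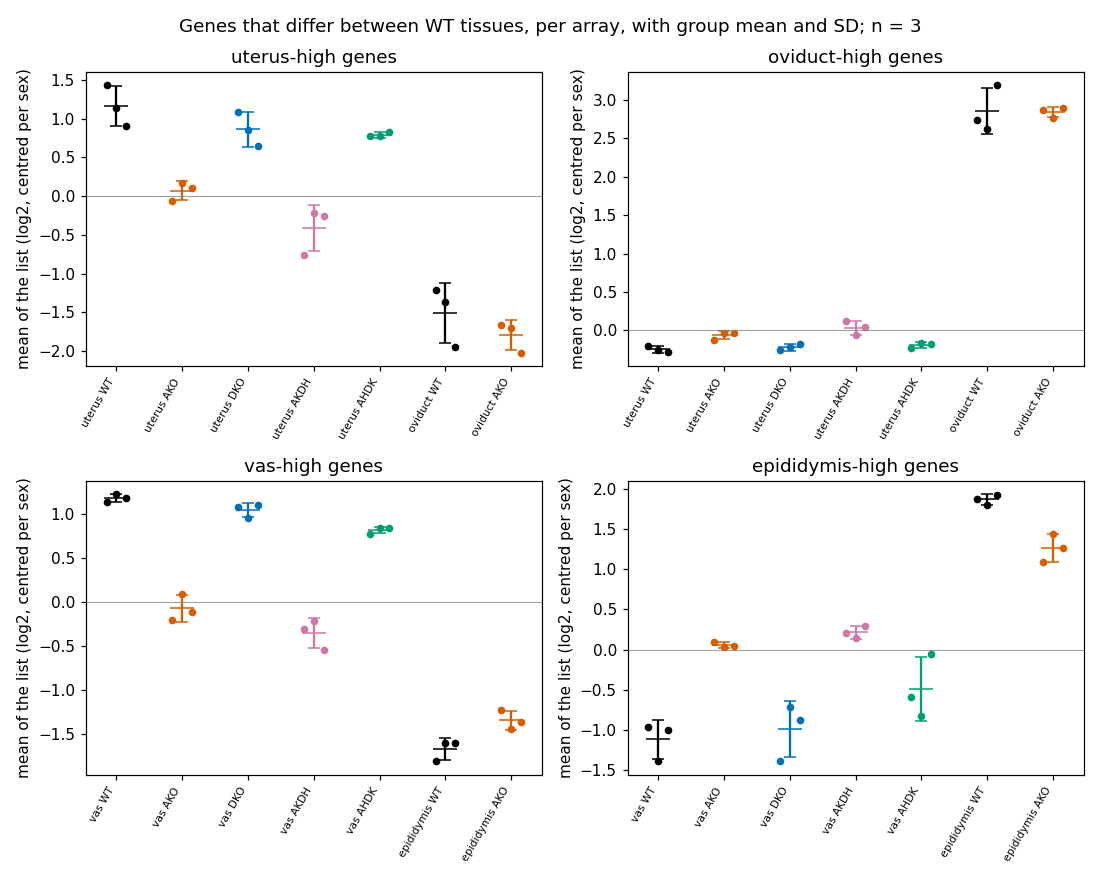
Mean of the uterus-high, oviduct-high, vas-high and epididymis-high genes (vertical axis, log2) in each array of the 2 tissues of a sex, with group mean and SD. AKO and AKDH vas lay between WT vas and WT epididymis, and AKO and AKDH uterus lay between WT uterus and WT oviduct for uterus-high genes.

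In oviduct AKO limma called 0 genes (smallest adjusted p 0.993; 609 at an unadjusted p below 0.05; 8.65% apart, 10% by chance), with or without the library labelled WT oviduct replicate 2. On simulated data of this size 72% of changes of 1 were recovered, and no smaller change was simulated. The simulated changes fell on genes drawn from all genes, in independent arrays, so recovery can be lower for genes of large spread. Camera called 11 lists lower at the preset correlation, each with 0 members called by limma, over all genes and over the list alone, and each at 0.989 with an estimated correlation. Among them were ovary genes (mean -0.92, adjusted p = 2.57e-06), BMP genes (-0.15, 0.00107) and endothelial genes (-0.25, 0.00784), all estimated at 0.989. Leaving out 1 array moved the mean of each of the 11 lists by more than 1.5 times: ovary genes had -0.32 without WT replicate 2, BMP genes -0.08 without AKO replicate 3, and endothelial genes -0.09 without AKO replicate 3 and -0.50 without WT replicate 3. In 3 of the 11 the direction turned: smooth muscle genes (-0.18) had 0.02 without AKO replicate 3, extracellular matrix genes (-0.23) 0.02 without WT replicate 2 and 0.06 without AKO replicate 3, and adipocyte genes (-0.43) 0.03 without WT replicate 1. These values ignore that WT and AKO arrays of the same number were correlated. Smooth muscle genes were lower in AKO at each number (-0.04, 0.03 and -0.74 in WT, -0.21, -0.25 and -0.83 in AKO). So were extracellular matrix genes (-0.20, 0.03 and -1.22, against -0.43, -0.38 and -1.28). Adipocyte genes were not (1.60, 0.22 and 0.22, against 0.49, 0.27 and 0).

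In epididymis AKO, Npy, a neuropeptide, fell most (-5.40, SE 0.16, adjusted p = 0.000581), with values of 5.03, 5.49 and 5.60 in WT and 0.09, -0.17 and 0 in AKO. The protamines Prm1 (-4.89) and Prm2 (-4.76) and the sperm genes Smcp (-4.38) and Odf1 (-3.91) fell. The protease inhibitors Spint4 (5.08, SE 0.39, adjusted p = 0.0107) and Spint5 (4.57), Epp13 (4.73) and the sulfotransferase Sult1d1 (4.70) rose most. Of 156 called genes 82 rose and 74 fell (3193 at an unadjusted p below 0.05; 22.1% apart, 10% by chance). Without the library labelled AKO epididymis replicate 1 there were 263, 167 up and 96 down, and Epp13 was then 4.14 and Npy -5.46. The count was 38 and 26 without WT replicates 2 and 3, 17 without AKO replicate 2, 17 without AKO replicate 3, and 9 with the replicate block.

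Sperm genes gave 6 falls of 30 in epididymis AKO, or 19 over the list alone (mean -1.65, camera adjusted p = 5.92e-16, and 0.989 with an estimated correlation). Smooth muscle genes gave 2 falls of 32, Des (-1.64) and Myocd (-1.18), or 20 over the list alone (mean -0.77, adjusted p = 1.99e-15, and 0.989 estimated). Cell cycle genes gave 4 rises of 31, among them Ccnb2 (0.90), Ect2 (0.77) and Plk1 (0.74), or 14 over the list alone (mean 0.36, adjusted p = 1.3e-10, and 0.989 estimated). Extracellular matrix genes had 0 of 45 called by limma both ways (mean -0.42, and -0.22 without WT replicate 1; adjusted p = 1.1e-09, and 0.989 estimated). Epididymis-high genes were lower (mean -0.60, SE 0.11, median -0.27), with 18 falls and 2 rises. Camera gave adjusted p = 6.05e-11 with the preset correlation and 0.27 with an estimated one, and the mean was -0.36 without WT replicate 1. That list also holds sperm genes, among them Prm1, Tnp2 and Akap4. Vas-high genes had a mean of 0.33 (SE 0.10; preset adjusted p = 0.0652, estimated 0.38), with 0.17 without WT replicate 1 and 0.20 without vas WT replicate 3.

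DKO and AKO uterus differed in 37 genes, 22 higher in DKO and 15 lower (2714 at an unadjusted p below 0.05). Slc26a7 (3.37), Rxfp2 (2.56), Robo2 (2.40) and Aldh1a2 (2.30) were higher in DKO, and Upk1a (-2.42), Rtn1 (-2.35), Fgf16 (-1.60) and Hoxc8 (-1.33) were lower. That count was 7, 15 and 150 without AKO replicates 1, 2 and 3, and 15 and 11 without DKO replicates 2 and 3. AHDK and DKO uterus differed in 5 genes (1489 at an unadjusted p below 0.05): Kap (3.40) and Smpd3 (0.84) were higher in AHDK, and Slc26a7 (-2.76), Rxfp2 (-2.60) and Cldn8 (-1.09) lower. Quantile normalisation gave 3 there, 2 up and 1 down. The 5 became 71, 1 and 2 without DKO replicates 1, 2 and 3, and 2 and 1 without AHDK replicates 1 and 3. AKDH and AKO uterus differed in 0 genes by limma (2063 at an unadjusted p below 0.05), and in 167 without AKO replicate 3, 32 without AKDH replicate 2 and 4 without AKDH replicate 3. Over the 4 uterus mutants together an F test called 888 genes (4753 at an unadjusted p below 0.05), and 494 and 454 without WT replicates 2 and 3, 565 and 586 without AKO replicates 1 and 2, 1333 and 585 without DKO replicates 1 and 3, 570 without AKDH replicate 3, and 240, 520 and 317 without AHDK replicates 1, 2 and 3.

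DKO and AKO vas differed in 3551 genes, 2280 higher in DKO and 1271 lower (1933 and 1754 after quantile normalisation; 6154 at an unadjusted p below 0.05). Ptprz1 (3.95), Akr1cl (3.08), Eci3 (2.93) and Hoxa11 (2.04) were higher in DKO, and Svs4 (-4.60), Svs3b (-4.34), Gpx5 (-4.30), Rnase9 (-3.82) and Axin2 (-1.19) were lower. The count was 2208 and 2210 without AKO replicates 1 and 3, and 2078 without DKO replicate 1. AKDH and AKO vas differed in 258 genes, 89 up and 169 down (247 and 237 after quantile normalisation), with Serpina3b (2.60) higher in AKDH and Svs3b (-3.57) lower. That was 72, 88 and 56 without AKO replicates 1, 2 and 3, and 52 without AKDH replicate 1. AHDK and DKO vas differed in 73 genes, 35 up and 38 down (43 and 7 after quantile normalisation; 181 without the libraries that stood apart), with Serpina3b (3.03) higher in AHDK and Cartpt (-1.74) lower. The 73 became 11, 13 and 7 without DKO replicates 1, 2 and 3, and 20 and 13 without AHDK replicates 1 and 3. An F test over the 4 vas mutants called 4811 genes.

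The AKO effect differed between epididymis and vas in 1439 genes, 791 with a higher change in epididymis and 648 with a lower one (4030 at an unadjusted p below 0.05; 902 without vas WT replicate 2, 916 without vas AKO replicate 3). Npy (-5.25), Rnase9 (-4.12), Gpr82 (-3.95), Znrf3 (-1.66) and Axin2 (-1.40) had the lower change in epididymis, and Defb30 (5.63), Lcn5 (5.43), Spint4 (5.08) and Sult1d1 (4.77) the higher. Between uterus and oviduct limma called 0 such genes (smallest adjusted p 0.216; 847 at an unadjusted p below 0.05), and 3 without the library labelled WT oviduct replicate 2. It called 2 without uterus WT replicate 2, 1 without oviduct WT replicate 3 and 1 without oviduct AKO replicate 2.

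Genes called in 2 mutants of a tissue mostly moved the same way. In uterus, AKDH and AHDK shared 341 same-direction genes, 173 up, among them Hoxc10 and Sfrp1, and 168 down, among them Rxfp2 and Eya1. Independent calls gave 18.0 and 6.51. DKO and AHDK shared 151 (97 up, 54 down, independent 2.85 and 0.864), with Retnlg, Ccr3 and Cldn8 among them, and DKO and AKDH 139 (77 up, 62 down, independent 4.87 and 1.85). AKO shared 16 with AKDH (7 up, 9 down, independent 0.314 and 0.265), 6 with AHDK (independent 0.184 and 0.123) and 3 with DKO (independent 0.0498 and 0.0351). Simulations with no change gave at most 0.05 shared genes on average. They held no changed gene, so a low count was fixed in advance and does not show what shared WT arrays add between changed mutants. Covariances of the changes were 0.0707 for AKO with AKDH (simulated 0.0205), 0.0661 for DKO with AHDK (0.0206), 0.0617 for AKDH with AHDK (0.0205), 0.0451 for DKO with AKDH (0.0207), 0.0408 for AKO with AHDK (0.0205) and 0.0291 for AKO with DKO (0.0207). Correlations, where the simulations gave 0.50, were 0.76 for AKO with AKDH, 0.72 for DKO with AHDK, 0.50 for AKDH with AHDK, 0.48 for DKO with AKDH, 0.46 for AKO with AHDK and 0.43 for AKO with DKO, so 4 of 6 did not exceed the value without change. All pairs shared their WT arrays, so part of each excess may come from shared controls. Leaving replicate 1, 2 or 3 out of every group brought the 341 to 46, 0 and 1, the 151 to 4, 0 and 0, and the 139 to 4, 0 and 0. The 16 became 28, 1 and 0, the 6 became 11, 0 and 0, and the 3 became 3, 0 and 0 (limma).

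In vas, AKO and AKDH shared 1631 same-direction genes, 846 up, among them Rnase9, Gpr82 and Axin2, and 785 down, among them Cdkl1, Eci3 and Nmu (independent 93.7 and 131), with 1 gene going opposite ways. AKDH and AHDK shared 755 (372 up, 383 down, independent 39.6 and 60.9), DKO and AKDH 660 (351 up, 309 down, independent 73.5 and 59.3; 23 opposite), and DKO and AHDK 376 (182 up, 194 down, independent 15.9 and 8.33; 1 opposite). AKO shared 347 with AHDK (187 up, 160 down, independent 20.3 and 18.4; 6 opposite) and 198 with DKO (113 up, 85 down, independent 37.7 and 17.9; 40 opposite). Gpr82 was up and Nmu down in all 4 vas mutants. Simulations with no change gave at most 0.05 shared genes on average, a low count that was again fixed in advance. Covariances were 0.13 for AKO with AKDH (simulated 0.0153), 0.071 for AKDH with AHDK (0.0153), 0.0475 for AKO with AHDK (0.0151), 0.0311 for DKO with AKDH (0.0155) and 0.0309 for DKO with AHDK (0.0152). For AKO with DKO the covariance was 0.0132, below the simulated 0.0154. Correlations were 0.87 for AKO with AKDH, 0.70 for AKDH with AHDK, 0.60 for DKO with AHDK and 0.57 for AKO with AHDK, against 0.50 or 0.51 simulated, and lower than simulated for DKO with AKDH (0.34) and AKO with DKO (0.18). Without replicate 1, 2 or 3 of every group the 1631 became 432, 299 and 970, the 755 became 9, 5 and 316, the 660 became 0, 3 and 318, the 376 became 0, 1 and 165, the 347 became 5, 2 and 156, and the 198 became 0, 0 and 119 (limma). Here too, part of each excess may come from shared controls.

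Over all 380 list tests, 63 were called at the preset correlation and 0 with an estimated one. Epididymis AKO lists with small means were targeted Hox genes (-0.56, camera adjusted p = 0.0023), BMP genes (-0.15, 0.014), stroma genes (-0.19, 0.0245) and interferon genes (-0.11, 0.0125), each at 0.989 estimated. Without epididymis WT replicate 1 the first 3 of these had means of -0.36, -0.09 and -0.10. The lists of oviduct AKO not given above were targeted Hox, Hedgehog, stroma, progesterone-responsive and cell cycle genes (means -0.53, -0.21, -0.17, -0.19 and -0.12, or -0.32, -0.07, -0.03, -0.11 without oviduct AKO replicate 3 for the first 4 and -0.04 without AKO replicate 2 for the last). Over all 63 calls, leaving out 1 array moved 25 means by more than 1.5 times in the same direction, turned 5 and left 33 within that range.

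Genes near the targeted clusters were not called more often than others. Of 20 tests (318 genes within 20 Mb of Hoxa, 457 of Hoxd), 2 passed, both with fewer called genes near Hoxd: 5.25% against 9.49% in vas AKO (odds ratio 0.529, adjusted p = 0.0147) and 10.9% against 24.7% in vas AKDH (odds ratio 0.375, adjusted p = 5.76e-12). Of 1027 olfactory receptor genes measured, 215 lay near Hoxd and 20 near Hoxa. Without them 0 of the 20 passed, with 10.3% against 9.96% in vas AKO and 19.8% against 25.3% in vas AKDH (unadjusted p = 0.0528, adjusted p = 1).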

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

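Of the tests in this part, the tests of the difference between tissues were planned, while the tests of mixed tissue, wrong sex, blood, cycle stage, small RNA and muscle, and the regroupings, were chosen after the results had been seen. One of them, the smooth muscle test, replaced a first form that had been run, into which too few muscle genes entered, and which had also argued against muscle.

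The AKO effect differed between epididymis and vas deferens in 1439 genes by limma's test of that difference. It was higher in epididymis for Defb30 (5.63, SE 0.81, adjusted p = 0.000747), Lcn5 (5.43, SE 0.79), Spint4 (5.08, SE 0.37) and Epp13 (4.90, SE 0.68). It was lower in epididymis for Npy (-5.25, SE 0.21, adjusted p = 3.04e-10), Mmp7 (-4.39, SE 0.79), Rnase9 (-4.12, SE 0.56) and Gpr82 (-3.95, SE 0.40). In WT these genes were higher in epididymis than in vas (5.27, 3.19, 5.66 and 3.98), so their changes started from unlike levels. The test of the difference singled out each of these 8 genes and the count. Defb30 was -2.60, -2.24 and -0.89 in WT epididymis and 2.62, 0.55 and 0.63 in AKO epididymis, against 2.03, 1.07 and 1.78 in WT vas and -1.46, -0.84 and -0.18 in AKO vas. Without the library labelled AKO epididymis replicate 1, Defb30 was 4.95, Lcn5 4.57, Spint4 5.01, Epp13 4.30, Npy -5.31, Mmp7 -4.86, Rnase9 -4.21 and Gpr82 -3.93, all still called. Of 100 regroupings 2 gave as many genes, the real one included; the highest other gave 1719 and exchanged the genotype labels of 1 tissue, which turns the difference of the effects into their sum.

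The library labelled WT oviduct replicate 2 had Xist at -5.92, Eif2s3y at 2.09, Uty at 1.77, and the ovary genes Cyp11a1 at 6.98 and Akr1c18 at 6.49. Male tract tissue in place of an oviduct was argued against, since 322 genes high in AKO oviduct kept 89% of their height in the other WT oviducts. Ovarian tissue mixed into the library may explain the ovary genes, whose mean of 2.06 over 20 genes lay 1.65 above the highest other oviduct array (0.41). Cells with 1 X chromosome and a Y chromosome may explain the sex-linked genes, as 5 genes that escape X inactivation lay -0.34 from the mean of the other arrays, the lowest of which lay at -0.12. XY tissue mixed into an XX oviduct was argued against, since Xist lay -5.50 from the lowest other oviduct array (2.21% of its signal) while the oviduct genes kept their height; how an oviduct library came to lack Xist stays open, and no biological explanation was tested.

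Means of the macrophage and neutrophil lists were above WT in uterus DKO and AHDK, called by camera at the preset correlation and not with an estimated one (adjusted p = 0.989). The B and plasma cell list was called so in DKO only, and the T, NK and mast cell list in AHDK only. Of 25 macrophage genes 2 were called in DKO and 10 in AHDK. More blood was argued against in AHDK only as far as 3 erythrocyte genes show it, the ones measured of 12 on the list. Their mean was 0.02 (SE 0.13), below 0.42, 50% of the macrophage change. Whether these genes stood above background is unknown after centring, so the argument is weak. More blood stays open in DKO, where they had 0.29 (SE 0.13) against 0.31. Cycle stage, as far as oestrogen-responsive genes measure it, stays open in both. With that score as a covariate the macrophage list was 0.96 in AHDK (SE 0.23, and 0.84, SE 0.18 without it). In DKO it was 0.67 (SE 0.20, and 0.61, SE 0.18 without it), within 2 SE of the 50% bound. Every AHDK array had a score above every WT array (0.99, 0.66 and 1.01 against -0.67, 0.63 and -0.28). Score and genotype were thus confounded in AHDK, and the covariate cannot remove a stage difference between them. The loss of small RNA signal (-0.13 in AKO, -0.25 in DKO, -0.29 in AKDH and -0.25 in AHDK, SE 0.05 each) could not be told apart from genotype, although AKDH had it with a macrophage change of 0.13 (SE 0.18). An effect of the genotypes themselves stays possible and was not tested beyond the comparisons, and Retnlg and Ccr3 changed less under the small RNA covariate (Retnlg 1.08 in DKO).

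Vas AKO and AKDH had lower vas-high genes, and higher epididymis-high genes at the preset correlation but not with an estimated one (adjusted p = 0.0564 and 0.064). Whole epididymis mixed into the libraries was argued against as the whole cause: the share set by the fall of the vas-high genes, 65.3%, needed a median change of 2.13 in AKO and 1.21 was seen, with a median gap of -1.25 (SE 0.04), or -0.56 (SE 0.02) with AKO epididymis as the source at 71.6%. Of 128 genes that such a mixture would raise by at least 2, 26 changed by less than 0.5. Of 109 with AKO epididymis as the source, 11 did, and only 5 genes did so with both sources. The 26 hold sperm genes, among them Tnp2 and Akap4, which AKO epididymis as the source would not raise (-0.57 and 0.06). Such genes do not weigh against mixed AKO epididymis, and they also enter the median gaps. Defb22 needed 5.45 or 5.79 and had 0.03. The gap with AKO epididymis lay only just beyond the bound set for this test, so the argument is weaker there. That source includes the library labelled AKO epididymis replicate 1, which stood apart, and both SEs cover the AKO vas arrays alone. A lower share of smooth muscle was argued against as the whole cause of the vas-high falls. Their median of -1.21 lay -0.59 (SE 0.07, from the AKO arrays alone) below that of the muscle list (-0.63), with 0 muscle genes among them. The vas-high genes were chosen on the same WT vas arrays, which can enlarge their fall and this gap. Tissue of the cauda epididymis may still contribute, because no cauda array exists here to set its levels and the list nearest to it (mean change 0.64) also holds genes of the vas epithelium, and a change of segment type in the mutants stays equally open.

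For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. Splits with as many genes, the real one included, numbered 1 in uterus AKO (18 real, 0 highest other), DKO (194 and 47), AKDH (1311 and 0) and AHDK (704 and 0). They numbered 1 in vas AKO (1865 and 0), DKO (1170 and 0), AKDH (4849 and 0) and AHDK (827 and 694), 10 in oviduct AKO (0 and 0 by limma, 609 at an unadjusted p below 0.05) and 1 in epididymis AKO (156 and 0). Between mutants they were 2 for uterus DKO against AKO (37 and 45), 10 for AKDH against AKO (0 and 0 by limma, 2063 at an unadjusted p below 0.05) and 2 for AHDK against DKO (5 and 13). In vas they were 1 for DKO against AKO (3551 and 0), 1 for AKDH against AKO (258 and 0) and 1 for AHDK against DKO (73 and 0). WT oviduct against uterus had 1 (4770 and 3), and WT epididymis against vas 1 (5602 and 1).

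With 100 regroupings each, the F tests gave 1 in uterus (888 real, 174 highest other) and 1 in vas (4811 and 2), which argues against chance labelling there. In uterus the small RNA score also set WT apart, and this test does not tell genotype from it. The epididymis and vas difference gave 2 (1439 real, 1719 highest other). Its regroupings also mixed the AKO effects within each tissue, so they do not test the difference alone. The uterus and oviduct difference gave 100 (0 real by limma, 847 at an unadjusted p below 0.05, highest other 27); a real count of 0 is always matched, so this test says nothing about chance. List calls gave 92 (63 real, 124 highest other), so other labellings of the same arrays called as many lists at the preset correlation, and those calls are not told from chance. Overlaps gave 1 of 100 for each pair, the real one. Relabelling also removed the genotype effects, so it does not show what shared WT arrays add between changed mutants. In uterus the overlaps were 3 (highest other 1), 16 (1) and 6 (1) for AKO with DKO, AKDH and AHDK, 139 (7) and 151 (11) for DKO with AKDH and AHDK, and 341 (8) for AKDH with AHDK. In vas they were 198 (0), 1631 (0) and 347 (0) for AKO with DKO, AKDH and AHDK, 660 (1) and 376 (1) for DKO with AKDH and AHDK, and 755 (2) for AKDH with AHDK.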

How the results depend on the processing

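Alternatives chosen after the data were seen were the spread filter, the small RNA, oestrogen, adipocyte and skeletal muscle covariates, the replicate block within genotype, gene lists with 1 array left out, the fits without libraries that stand apart, the other probe set rules, segment lists without the targeted genes, and the windows without olfactory receptor genes; the rest were planned. Of 759 alternative values for 56 results, 533 stayed the same in call and size, 14 lost a call, 16 gained one, 191 counts moved by more than 1.5 times and 5 reversed. Named genes had 45257 alternative values, of which 41900 stayed, 2863 lost a call, 492 gained one and 2 reversed. Among 930 called named values, 382 lost the call with 1 array left out and 634 in another alternative. The planned filter on dim probe sets was not run. The cause of a move was not tested unless given.

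An eBayes trend gave 7 genes in uterus AKO, 0 in uterus AHDK against DKO (limma; 1489 at an unadjusted p below 0.05 in the fit without it) and 22 in vas AHDK against DKO. Fits of 2 groups, with fewer arrays to estimate spread, gave 1, 0 and 82 in uterus AKO, DKO and AKDH (3048 at an unadjusted p below 0.05 for DKO in the limma fit of all groups). In vas they gave 2841 in AKDH and 0 in AHDK (3520 at an unadjusted p below 0.05 in that same limma fit), and 3058 for WT oviduct against uterus. Between mutants they gave 1 for uterus DKO against AKO, 1 for AHDK against DKO, 0 for vas AKDH against AKO (2824 at an unadjusted p below 0.05 in limma) and 4 for AHDK against DKO.

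The spread filter gave 49 in uterus AKO, 55 in uterus DKO, 581 in vas DKO, 56 for uterus DKO against AKO and 11 for AHDK against DKO, 108 for vas AKDH against AKO and 36 for AHDK against DKO. Uterus overlaps were then 7, 45 and 18 for AKO with DKO, AKDH and AHDK, and 43 and 53 for DKO with AKDH and AHDK. Vas overlaps were 109 for AKO with DKO, and 335 and 218 for DKO with AKDH and AHDK. Of the cluster tests 0 passed with the spread filter, 0 in 10 Mb windows and 0 without olfactory receptor genes, while 3 passed in 40 Mb windows, each with fewer called genes near Hoxd (vas AKO, AKDH and AHDK, adjusted p = 0.0012, 7.26e-15 and 0.0281).

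Small RNA covariate: 9, 0, 1 and 0 in uterus AKO, DKO, AKDH and AHDK (limma; 1865, 3048, 4528 and 4260 at an unadjusted p below 0.05 without it), 3 for DKO against AKO, 3 for AHDK against DKO and 117 by the F test, with Id4 at -0.11 and Cd79b at -0.06 reversed in AKDH. Oestrogen covariate: 111 in uterus AKO, 88 in AHDK, 100 for DKO against AKO and 1 for AHDK against DKO. Adipocyte and skeletal muscle covariates: 345, 254, 266 and 1 in vas AKO, DKO, AKDH and AHDK, 1062 for DKO against AKO, 9 for AKDH against AKO, 1 for AHDK against DKO and 1238 by the F test. The replicate block, a pairing by number, gave 9 in epididymis AKO, 18 for uterus DKO against AKO, 4 for AKDH against AKO, 141 for vas AKDH against AKO and 18 for AHDK against DKO. Without the libraries that stand apart there were 263 in epididymis AKO, 181 for vas AHDK against DKO and 3 for the uterus and oviduct difference.

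Quantile normalisation gave 12, 837 and 375 in uterus DKO, AKDH and AHDK, 438 in vas DKO, 59, 10 and 3 for uterus DKO against AKO, AKDH against AKO and AHDK against DKO, 484 for vas AKDH against AKO and 7 for the uterus and oviduct difference. Uterus overlaps became 1 for AKO with DKO, 10 and 12 for DKO with AKDH and AHDK, and 149 for AKDH with AHDK. Vas overlaps became 89 and 206 for AKO with DKO and AHDK, and 287 and 190 for DKO with AKDH and AHDK. Oviduct-high genes in uterus AKO (0.18) and vas-high genes in vas DKO (-0.16) lost their call, while uterus-high genes in AHDK (-0.92) and vas-high genes in epididymis AKO (0.19) gained one.

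Lists chosen and measured on different WT arrays gave 0.12, 0.20 and 0.01 (reversed) for oviduct-high genes in uterus AKO, AKDH and oviduct AKO. They gave -0.35, 0.40 (reversed) and -0.41 for uterus-high genes in AKO, DKO and oviduct AKO, -0.41 for epididymis-high genes in epididymis AKO and -0.03 for vas-high genes in vas DKO. At a list threshold of 1, uterus-high genes in AHDK were -0.44 (gained) and vas-high genes in vas DKO 0.02 (reversed). An estimated correlation left 0 of the 63 gene list calls, while 4 segment list calls stayed.

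With 1 array left out, lowest and highest counts were 2 and 40 in uterus AKO, 2 and 133 in DKO, 530 and 1207 in AKDH, and 31 and 505 in AHDK. They were 1018 and 1767 in vas AKO, 238 and 1323 in DKO, 3032 and 4708 in AKDH, 245 and 867 in AHDK, and 17 and 263 in epididymis AKO. Between uterus mutants they were 7 and 150 (DKO against AKO), 0 and 167 (AKDH against AKO), 1 and 71 (AHDK against DKO), and 240 and 1333 (F test). Between vas mutants they were 2078 and 2697, 52 and 240, 7 and 94, and 3523 and 5272 in the same order. The uterus and oviduct difference ran from 0 to 3, the epididymis and vas difference from 902 to 1353, WT oviduct against uterus from 2955 to 4398 and WT epididymis against vas from 4532 to 5056. For list means, oviduct-high genes ran from 0.16 to 0.25 in uterus AKO and -0.13 to 0.10 in oviduct AKO (0.10, reversed, without oviduct WT replicate 3). Uterus-high genes ran from -0.63 to -0.07 in DKO, -1.11 to -0.21 in AHDK and -0.46 to 0.02 in oviduct AKO (0.02, reversed, without oviduct WT replicate 1). Epididymis-high genes ran from -0.01 to 0.33 in vas DKO, and vas-high genes from -0.29 to -0.08 there and 0.17 to 0.36 in epididymis AKO. Called gene lists with 1 array left out moved in 25 of 63 cases and turned in 5. With 1 replicate number left out of all groups, uterus overlaps ran from 0 to 3, 0 to 28 and 0 to 11 for AKO with DKO, AKDH and AHDK, 0 to 4 for DKO with AKDH and with AHDK, and 0 to 46 for AKDH with AHDK. Vas overlaps ran from 0 to 119, 299 to 970 and 2 to 156 for AKO with DKO, AKDH and AHDK, 0 to 318 and 0 to 165 for DKO with AKDH and AHDK, and 5 to 316 for AKDH with AHDK.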

Other observations

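All comparisons of single genes with other tissues in this part were chosen after the results had been seen. Several genes of uterus AKO stood on the side of WT oviduct. Rxfp2 fell by 2.78 in AKO and was -2.97 in WT oviduct against WT uterus, Robo2 fell by 2.61 and was -2.83, and Tnfaip6 fell by 1.43 and was -1.33. Hoxc8 (1.46 in AKO, 3.46 in WT oviduct), Fgf18 (1.31 and 1.36) and Upk1a (2.63 and 4.32) went the other way in the same manner, while Hoxc10 rose by 1.86 and was not called between the WT tissues (0.48). The uterus-high list shrank to -0.35 and lost its call in AKO when it was chosen and measured on different WT arrays, and kept its call in AKDH at -0.82, so a move of the AKO uterus toward oviduct may be partly a matter of the shared WT arrays.

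Among Wnt genes, 2 stood out in vas AKO and AKDH. Axin2 rose by 1.22 in AKO and 1.28 in AKDH, and Znrf3 by 1.30 and 1.70, and both were higher in WT epididymis than in WT vas (1.76 and 1.36). Both were called in AKO and AKDH in every alternative run, and Znrf3 also rose in DKO (0.88) and AHDK (0.74). The list of 61 Wnt genes as a whole was not called in AKO (7 rose, 5 fell; camera adjusted p = 0.614, and 0.989 with an estimated correlation) or AKDH (mean -0.08; 10 rose, 8 fell; 0.843, and 0.989 estimated). Not all genes of the vas changes were epididymis genes: Svs3b rose by 3.66 in AKO and was -0.55 between WT epididymis and WT vas (adjusted p = 0.55). Svs3b is a seminal vesicle gene, and it was called lower in AKDH than in AKO, although both lack the same Hoxa genes. Seminal vesicle and prostate genes also varied between arrays of 1 genotype, with -0.44, 0.05 and 1.13 in WT vas and 1.06, 1.16 and 1.78 in AKO. The cause of the Svs3b rise was not tested.

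Of 19 adipocyte genes, 12 rose in vas AKO, 15 in AKDH and 13 in AHDK, while the list was called at the preset correlation and not with an estimated one (adjusted p = 0.989 in each). With adipocyte and skeletal muscle scores as covariates 345 genes were called in AKO, 266 in AKDH and 1 in AHDK. The changes themselves did not shrink for 2 genes outside the scores: in AHDK, Gpr82 went from 2.74 to 3.48 and Rnase9 from 2.31 to 3.89, neither called any more. Every AKO, AKDH and AHDK array had an adipocyte score above every WT array, so score and genotype were confounded and the lost calls do not show an effect of fat. In epididymis AKO, Prm1 and Prm2 fell with other sperm genes, and Npy, Prm1 and Sult1d1 were called in every alternative run.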
